A study of Mus musculus with 12 samples.

How the data were processed

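RNA of adipose tissue was measured in 12 samples of C57Bl/6 mice, 4 on chow, 4 after 5 days and 4 after 14 days of HFD. Per the labels, total RNA was turned into complementary DNA with an oligo(dT) primer carrying a T7 promoter, transcribed into biotin-labelled RNA and hybridised to single-colour Affymetrix arrays, 1 sample per array. The authors deposited 1 table with 45098 probe sets. Its values are in log2 units as deposited by the authors, judged from their range from 4.18 upward, their near-equal distribution in each array and the scanner's upper limit. How the authors summarised probes and normalized arrays is not stated, and nothing was renormalized for the values reported. Array medians ran from 8.09 to 8.14. Arrays give no counts, so precision is set by their number.

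Probe sets were named with the platform annotation of the array. Of the 45098 probe sets, 61 were controls, 34945 carried 1 gene symbol, 932 several and 9160 none. Named probe sets were matched to RefSeq genes of GRCm38.p6 by Entrez ID in 34741 cases, which changed 0 symbols. Each of 18193 genes was represented by the probe set with the highest mean over all arrays, and genes under the 40th percentile of probe set means (7.64 log2) were left out, which kept 13312. Probe sets with several symbols were not used. Probe sets with no symbol were tested on their own.

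The 3 groups were fitted together with limma 3.58.1 in R 4.3.3, with a moderated variance that follows the mean signal (eBayes with trend), and compared as 5 days against chow, 14 days against chow and 14 against 5 days. All tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Before the data were examined, 23 pathway lists and 18 marker lists of cell types and neighbouring tissues were fixed, and 40 with at least 4 measured genes were tested; the sex chromosome markers were read only as levels. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 40 lists, and again with the correlation estimated for each list and with fry. Camera asks whether a list moved relative to the other genes; fry asks whether its genes moved one way on balance. List means were compared by an exact permutation test over the 70 labelings of 8 arrays, whose smallest p is 0.0286. None of the lists passed with an estimated correlation (0, 0 and 0 lists), with fry (0, 0 and 0) or with the exact test adjusted over 40 lists (lowest adjusted p 0.229, 0.286 and 0.686), against 9, 12 and 17 lists with the preset correlation. Counts adjusted over the list alone use the members of 1 list as the family.

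Named genes were chosen by a rule fixed before the data were examined. Because under 5 genes passed in each comparison, the 5 of smallest p in each direction were named, then up to 4 members of smallest p from each list, and 14 genes of interest at every comparison; the text names part of these. Spike-in probe sets, Alb, Gpx5 and the genes Foxj1, Cldn2 and Tmem212 stand outside that rule and were picked after their values were seen. The cell cycle genes Mcm4 and Mcm6, as named at 5 days against chow, also stand outside the limit of 4 members per list.

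Alternatives were median-centred and quantile-normalized arrays, no filter and a 60th percentile filter, the mean of a gene's probe sets, every probe set on its own, eBayes without trend and in robust form, array weights, only the 2 groups compared, the replicate number as a block, an adjusted p threshold of 0.1, and leaving out each array in turn. Covariates for epididymis, liver and skeletal muscle marker means, and leaving out both HFD arrays numbered 4, were added after the data were seen. Group labels were also permuted over the 35 splits of 8 arrays. The procedure was tested on simulated data made from the shuffled residuals of these arrays, with 200 changed genes in each of 20 draws. It recovered 55.1%, 54.7% and 56.0% of genes changed by 0.5 log2 units in the 3 comparisons. At 1 log2 unit it recovered 88.9%, 87.5% and 89.8%, and at 2 log2 units 96.4%, 95.5% and 96.3%. Changes of all these sizes were mixed in each draw, and a mean of 174.1, 171.55 and 175.6 genes was called. Many large changes ease the adjusted threshold, so these rates do not give the power where 0 genes are called. A list of 20 genes shifted by 0.5 was recovered in 20 of 20 draws. The genes of that list and of 39 unshifted lists were drawn at random, and 0 of the unshifted lists were called. Genes of the real lists move together, and other splits of the real arrays gave a median of 9, 15 and 13 called lists. The simulation therefore cannot tell how often camera calls an unshifted real list.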

Results

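Adipose tissue of C57Bl/6 mice was profiled on 12 single-colour Affymetrix expression arrays, 4 in each of 3 groups. Chow mice ate a diet holding 13% fat by calories throughout. The other groups were moved to a high-fat diet (HFD) holding 46% fat by calories at an age of 6 weeks and stayed on it for 5 or 14 days. The series title places the study in work on insulin resistance, with chow as the control for a time course of HFD. The fat depot is not named. The age of the chow mice at collection is not given, so age was not tested apart from diet in any comparison. Deposited log2 signals began at 4.18, array medians lay between 8.09 and 8.14, and correlations between pairs of arrays ran from 0.956 to 0.997. Precision is limited by the 4 arrays per group. Nothing in the labels says that each array came from a separate animal beyond calling them replicates. Each p of limma and of the exact permutation test below therefore measures the spread between these samples. A camera p at the preset correlation of 0.01 takes the genes of a list as nearly independent and can lie far lower. For macrophage markers at 14 days against chow, camera gave adjusted p = 1.89e-14 and the exact permutation test p = 0.0286. In all comparisons 13312 genes were tested, and log2 differences are given with their standard error (SE) from limma.

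Transcripts of neighbouring tissues differed strongly between arrays of the same group. Spink8 and Adam7, genes of the epididymis, stood at 14.28 to 14.45 and 13.07 to 13.29 in 5-day arrays 1 to 3 and at 14.96 and 13.89 in 14-day array 4. In 5-day array 4 Spink8 stood at 7.20, and in chow it ran from 7.12 to 8.38. The mean of the 4 measured epididymis and testis markers was 7.67 ± 0.56 in chow, 10.26 ± 2.07 after 5 days and 8.80 ± 2.69 after 14 days (SD, n = 4). Of these 4 genes, Gpx5 stayed between 7.82 and 8.52 in all arrays. Against chow, Spink8 differed by 4.98 ± 1.91 and Adam7 by 3.53 ± 1.52 at 5 days. Liver markers, among them albumin (Alb, 10.04 to 14.56), averaged 10.28 ± 1.78, 11.47 ± 1.69 and 11.22 ± 1.72 in chow, 5-day and 14-day arrays. Of these markers Cyp2e1 stayed between 14.88 and 15.04 in all arrays. The fibrinogen gene Fga differed by 2.51 ± 1.32 at 5 days. Skeletal muscle markers averaged 12.73 in chow array 3 and 12.45 in 5-day array 2, and between 8.41 and 9.47 in the other arrays. Smooth muscle markers reached 13.11 in 14-day array 4, 11.83 and 11.82 in 5-day arrays 1 and 2 and 10.87 in 14-day array 2, against 10.37 ± 0.24 in chow. None of Spink8, Adam7 and Fga passed the test at 5 days.

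**Figure D1:**
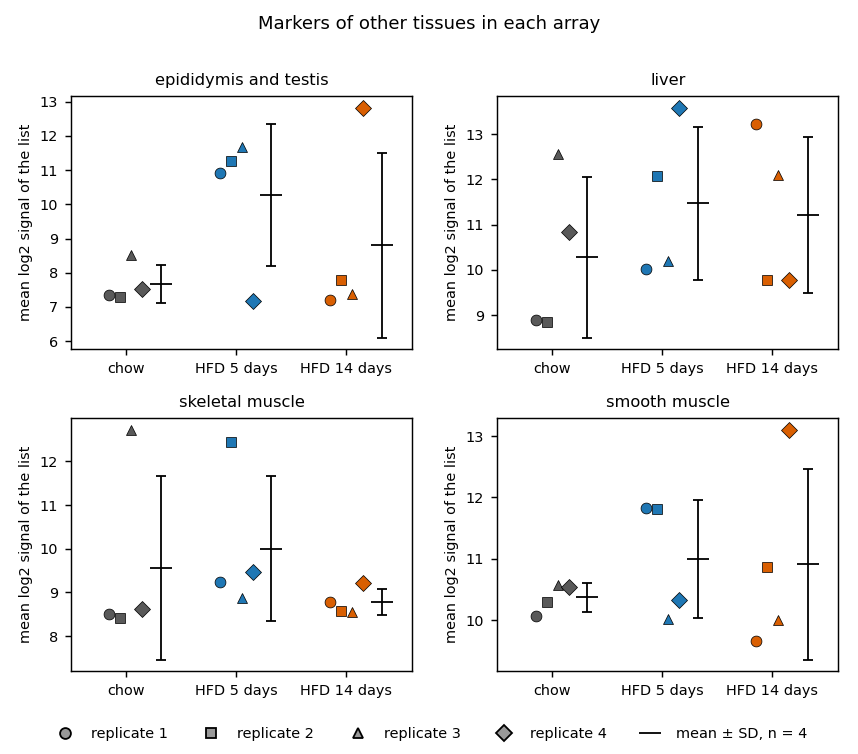
Mean log2 signal of the epididymis, liver, skeletal muscle and smooth muscle marker lists in each of the 12 arrays, by diet group; points are arrays with the marker shape giving the replicate, and bars are the mean ± SD (n = 4). Epididymis markers stand at 10.90 to 11.68 in 5-day arrays 1 to 3 and at 12.82 in 14-day array 4, and at or under 8.50 in all the others.

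The comparison of 5 days of HFD with chow asks what the diet altered early. Genes of cholesterol synthesis were higher, 19 of the 20 measured, with a median log2 difference of 0.19 and array means of 10.14 ± 0.03 against 9.85 ± 0.05 (SD, n = 4). The sterol reductase gene Tm7sf2 differed by 1.13 ± 0.36, Insig1, which restrains the sterol-sensing SREBP pathway, by 0.51 ± 0.13, and the synthesis enzymes Msmo1 and Cyp51 by 0.38 ± 0.14 and 0.32 ± 0.14. Circadian clock genes were lower, 11 of 14, with a median of −0.21 and array means of 10.45 ± 0.08 against 10.63 ± 0.03. The clock output factors Dbp, Hlf and Tef differed by −0.47 ± 0.11, −0.42 ± 0.13 and −0.20 ± 0.06, and the clock repressor Nr1d2 by −0.22 ± 0.07. Mesothelial markers, which belong to the covering layer of visceral fat, were lower in 8 of 10 members, with a median of −0.60, among them the transcription factors Bnc1 (−0.93 ± 0.26) and Wt1 (−0.68 ± 0.19) and the membrane proteins Gpm6a (−0.82 ± 0.26) and Lrrn4 (−0.84 ± 0.27).

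By camera (limma), the cholesterol synthesis list rose at adjusted p = 8.07e-05, but adjusted p = 0.599 with an estimated correlation. An exact permutation test of its array means gave p = 0.0286, the smallest that 4 arrays against 4 can give. The circadian clock list fell at adjusted p = 0.0013, with adjusted p = 0.599 with an estimated correlation and exact permutation p = 0.0286. Within the clock list, 7 genes were lower and 1 higher when adjusted over the list alone, and the hour of tissue collection is not given. The mesothelium list fell at adjusted p = 0.00058, with adjusted p = 0.599 with an estimated correlation and exact permutation p = 0.0571; 4 of its genes were lower when adjusted over the list alone. Its mean shift went from −0.45 to −0.30 without 5-day array 4. With epididymis, liver and skeletal muscle marker means as covariates, a setting chosen after seeing the data, the cholesterol synthesis shift was 0.12 (adjusted p = 0.185) and the circadian clock shift −0.057 (adjusted p = 0.37), while the mesothelium list stood at −0.48 and kept its call (adjusted p = 0.0115). In the same arrays epididymis markers were higher by a mean of 2.59 and liver markers by 1.19, with camera adjusted p = 0.0911 and 0.238. As single arrays were left out the epididymis and testis mean ran from 2.11 to 3.61 and passed in 3 of 12 fits (adjusted p = 0.0415 without 14-day array 4). The liver mean ran from 0.48 (without 5-day array 4) to 1.95 and passed in 2 of 12.

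Antigen presentation genes were lower in 11 of 12 members, with a median of −0.20 and array means of 11.96 ± 0.06 against 12.16 ± 0.09. The peptide transporter Tap2 differed by −0.38 ± 0.11 and the immunoproteasome subunits Psmb8 and Psmb9 by −0.42 ± 0.12 and −0.44 ± 0.13. Interferon response genes were lower in 15 of 16 members, with a median of −0.16, and Oasl2, an interferon-induced gene, differed by −0.60 ± 0.14. Mast cell markers were lower in 6 of 6 members, with the chymase gene Cma1 at −0.35 ± 0.12 and the histidine decarboxylase gene Hdc at −0.75 ± 0.27. Cytokine, chemokine and inflammatory genes were lower in 18 of 21 members, with a median of −0.11 and a mean of −0.0093; the adhesion molecule gene Icam1 differed by −0.40 ± 0.12 and the receptor gene Tlr2 by −0.37 ± 0.12.

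Camera gave adjusted p = 0.00426 for antigen presentation, 0.00242 for the interferon response, and 0.0224 for both the mast cell and the cytokine lists. Each had adjusted p = 0.894 with an estimated correlation, except the mast cell list with adjusted p = 0.768. Adjusted over the list alone, 3 antigen presentation genes and 1 interferon response gene were lower. The interferon response call ended without chow array 4 (mean −0.10, adjusted p = 0.064), and its mean was −0.12 without chow array 3. The cytokine and mast cell calls ended without 5-day array 4 (highest adjusted p = 0.234) and under quantile normalization (adjusted p = 0.0668 for the cytokines chemokines and inflammatory genes and 0.066 for the mast cell list). Array weights ended both (adjusted p = 0.0563 and 0.214), a 60th percentile filter the cytokine call (adjusted p = 0.0869) and a fit of only these 2 groups the mast cell call (adjusted p = 0.051). The mean of the cytokine list ran from −0.084 to 0.051 as single arrays were left out. In 5-day array 4 the difference between 3' and 5' probe sets of pyruvate carboxylase, a sign of RNA quality, was 2.83, against 1.70 to 1.91 in chow. With the epididymis marker mean as a covariate, added after seeing the data, antigen presentation stood at −0.093 (adjusted p = 0.073) and the interferon response at −0.071 (adjusted p = 0.0776). With 3 tissue covariates antigen presentation stood at 0.032 (adjusted p = 0.901) and the interferon response at −0.24 (adjusted p = 0.00109). In that fit the cytokine and mast cell calls ended (adjusted p = 0.494 and 0.25), and the macrophage list stood at 0.36 and was called higher (adjusted p = 0.000448).

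Oxidative phosphorylation genes were higher at 5 days in 22 of 27 members, with a median of 0.046, among them the respiratory chain subunits Ndufa1 (0.21 ± 0.06) and Cox4i1 (0.19 ± 0.07). Glycolysis genes were higher in 9 of 11 members, with a median of 0.12 and the triosephosphate isomerase gene Tpi1 at 0.40 ± 0.14. Fatty acid oxidation (14 of 21 higher) and branched-chain amino acid breakdown (12 of 16 lower) were not called, with camera adjusted p = 0.795 and 0.238. For oxidative phosphorylation and glycolysis camera gave adjusted p = 0.0228 and 0.0254, and adjusted p = 0.954 and 0.894 with an estimated correlation. Both calls ended without chow array 4 (adjusted p = 0.108 for each) and without 5-day array 2 (adjusted p = 0.0958 and 0.0762), and under quantile normalization (adjusted p = 0.162 for oxidative phosphorylation and nucleotide exchange and 0.066 for glycolysis). The glycolysis call also ended with the mean of a gene's probe sets (adjusted p = 0.0643) and with array weights (adjusted p = 0.0629).

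No single gene passed at 5 days: limma called 0 of 13312 genes at adjusted p under 0.05, with 1345 at unadjusted p under 0.05 (590 higher, 755 lower) and a lowest adjusted p of 0.248. In 11.3% of genes all 4 arrays of 1 group lay above all 4 of the other, where chance gives 2.86%. Genes move together, so such counts vary widely between groupings and show no excess by themselves. With chow array 1 in place of 5-day array 4, limma gave 1651 genes at unadjusted p under 0.05, more than the real 1345. The smallest p belonged to 2810459M11Rik (probe set 1452354_at, chromosome 1, 86045863 to 86055456, GRCm38.p6), at 8.48 ± 0.28 against 9.31 ± 0.15 (SD, n = 4) and a difference of −0.83 ± 0.12. The cyclin-dependent kinase subunit gene Cks2 (probe set 1417457_at, chromosome 13, 51645232 to 51650662) stood at 9.08 ± 0.27 against 7.99 ± 0.12, a difference of 1.09 ± 0.17. The other genes of smallest p were higher for Mrps6, a mitochondrial ribosomal protein (0.74 ± 0.13), the ceramide synthase Cers4 (0.50 ± 0.09), Cdca3 (0.36 ± 0.07, −0.11 at its second probe set) and Ostm1 (0.33 ± 0.06). They were lower for Cxxc5 (−0.43 ± 0.07), Podn (−0.64 ± 0.11), the transcription factor Osr1 (−0.68 ± 0.12) and the sialyltransferase St3gal6 (−0.65 ± 0.11, with 3 probe sets from −0.65 to −0.095). Counts rose to 2015 genes with array weights, 213 when only these groups were fitted and 123 without 14-day array 4. The last 2 counts differ from 0 only in the arrays that set the spread, since chow and 5-day arrays are all kept.

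None of the genes fixed for every comparison passed at 5 days. Leptin (Lep), secreted with fat mass, differed by 0.49 ± 0.29, and Mest and Sfrp5, which track fat mass expansion, by 0.68 ± 0.31 and 0.59 ± 0.45. The adipocyte genes Adipoq and Slc2a4 differed by −0.042 ± 0.04 and 0.10 ± 0.16, and the lipid synthesis genes Fasn and Scd1 by −0.012 ± 0.23 and 0.035 ± 0.03; Fasn turned to 0.0020 in median-centred arrays. The macrophage gene Adgre1 and the cytokine genes Ccl2 and Tnf differed by −0.10 ± 0.23, −0.13 ± 0.18 and −0.086 ± 0.08. Hif1a, Slc25a5 and Nos2 differed by 0.086 ± 0.07, 0.074 ± 0.06 and 0.012 ± 0.08, and the 4 probe sets of Hif1a ran from −0.15 to 0.086. Ucp1 averaged 7.13, under the intensity filter of 7.64. Fatty acid synthesis, triglyceride storage and insulin signalling genes were not called, with camera adjusted p of 0.795, 0.795 and 0.365, nor were adipocyte identity genes, with a median of −0.042 and exact permutation p = 0.743. The lipid-handling macrophage (8 of 11 higher), neutrophil (4 of 7 higher), T and NK cell (7 of 7 lower) and B cell (5 of 7 lower) lists were not called, with camera adjusted p = 0.398, 0.916, 0.435 and 0.653. The macrophage list was not called either, with 18 of 21 members lower and adjusted p = 0.123; its gene Cd14, a receptor subunit for bacterial lipopolysaccharide, differed by −0.54 ± 0.13. The macrophage list passed as lower in 3 of 12 fits without a single array, among them the fit without 14-day array 4, an array outside this comparison (adjusted p = 0.011), and when only these 2 groups were fitted (adjusted p = 0.00451). Its mean was −0.086 without 5-day array 4. Insulin signalling passed as lower without 5-day array 4 (adjusted p = 0.0414) and with array weights (adjusted p = 0.0311), and branched-chain amino acid breakdown with array weights (adjusted p = 0.0183).

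The tissue covariates, chosen after seeing the data, turned the balance of directions at 5 days. Camera called 9 lists without them, 3 of these higher, against 14 with the epididymis covariate, 10 higher, and 16 with the 3 covariates, 13 higher. In the 2 fits in that order the extracellular matrix mean of 0.10 was 0.35 and 0.42 (adjusted p = 1.55e-05 and 3.75e-12), and that of fat mass expansion, 0.38, was 0.76 and 0.51 (adjusted p = 0.00106 and 0.00109). Fatty acid oxidation went from −0.011 to 0.15 and 0.094 (adjusted p = 0.00106 and 0.00182), and branched-chain amino acid breakdown from −0.065 to 0.13 and 0.12 (adjusted p = 0.0397 and 0.0115). Triglyceride storage and lipolysis went from −0.0057 to 0.17 in both (adjusted p = 0.00923 and 0.00105), and adipocyte identity from 0.017 to 0.24 in both (adjusted p = 0.0285 and 0.00109). Lipid-handling macrophage markers went to 0.17 and 0.20 (adjusted p = 0.0346 and 0.00217) and heat shock genes to −0.24 and −0.23 (adjusted p = 0.0285 and 0.00182). Only the 3 covariates called the cell cycle (0.28), immediate early genes (0.21), endothelium (0.42) and preadipocyte and fibroblast markers (0.29) higher, and they ended the glycolysis call (adjusted p = 0.0912). Every camera p of a fit with covariates, at all comparisons, used the preset correlation only. In the fit without covariates the estimated correlation was 0.515 for the extracellular matrix and 0.744 for adipocyte identity, and no list passed with it. Covariates also widened errors: the SE of the cholesterol synthesis mean went from 0.083 to 0.138 with all 3.

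The comparison of 14 days of HFD with chow asks what the longer diet altered. Interferon response genes were lower in 16 of 16 members, with a median of −0.37 and array means of 9.19 ± 0.10 against 9.58 ± 0.24 (SD, n = 4); Zbp1, Oas1a and Xaf1, all interferon-induced, differed by −0.38 ± 0.09 (−0.15 at the second probe set of Zbp1), −0.27 ± 0.07 and −0.46 ± 0.14. Antigen presentation genes were lower in 12 of 12, with a median of −0.53 and array means of 11.75 ± 0.24 against 12.16 ± 0.09; the class II genes Cd74 and H2-Ab1 differed by −0.67 ± 0.18 and −0.68 ± 0.19, and Psmb8 and Psmb9 by −0.56 ± 0.12 and −0.50 ± 0.13. Macrophage markers were lower in 21 of 21, with a median of −0.49 and array means of 10.16 ± 0.49 against 10.67 ± 0.08; the complement gene C1qc differed by −0.78 ± 0.26, Ms4a7 by −0.33 ± 0.11 and Folr2 by −0.64 ± 0.22. Mast cell markers were lower in 6 of 6, with a median of −0.36; the protease genes Mcpt4, Cpa3 and Cma1 differed by −0.37 ± 0.10, −0.36 ± 0.10 and −0.42 ± 0.12, and Hdc by −0.72 ± 0.27. Cytokine, chemokine and inflammatory genes were lower in 19 of 21, with a median of −0.27; the chemokine genes Ccl8 and Cxcl10 differed by −0.70 ± 0.14 and −0.37 ± 0.11, and Tlr2 and Icam1 by −0.46 ± 0.12 and −0.44 ± 0.12.

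Camera called all 5 of these lists lower, with adjusted p = 3.06e-13 for the interferon response, 6.47e-12 for antigen presentation, 1.89e-14 for macrophage markers, 3.27e-06 for mast cell markers and 1.23e-06 for cytokines. With an estimated correlation the adjusted p = 0.21, 0.209, 0.326, 0.209 and 0.21 in that order. Exact permutation p was 0.0286 for the first 4 lists, with every 14-day array below every chow array, and 0.114 for cytokines. The lipid-handling macrophage, neutrophil, T and NK cell and B cell lists were not called (camera adjusted p = 0.0509, 0.104, 0.34 and 0.579). The first passed as lower in 6 of 12 fits without a single array, and its mean of −0.11 was −0.022 without 14-day array 4 (adjusted p = 0.554). The neutrophil list and the T and NK cell list each passed as lower in 1 of the 12, and the neutrophil list in 3 of 10 other planned settings; the B cell list passed as higher with 3 tissue covariates (mean 0.30, adjusted p = 0.0401). Adjusted over the list alone, 10 interferon response, 8 antigen presentation, 1 macrophage, 4 mast cell and 4 cytokine genes were lower. All 5 calls held as each single array was left out, and the macrophage mean of −0.51 was −0.27 without 14-day array 4, the array with the highest epididymis markers. The pyruvate carboxylase difference, a sign of RNA quality, was 1.96, 2.18 and 2.10 in 14-day arrays 1, 2 and 4. It was 1.72 in 14-day array 3, against 1.70 to 1.91 in chow. With the 3 tissue marker means as covariates, added after seeing the data, the cytokine call ended (mean 0.11, adjusted p = 0.411) and the macrophage shift was −0.14 (adjusted p = 0.0242). The interferon response, antigen presentation and mast cell lists stood at −0.46, −0.25 and −0.28 in that fit (adjusted p = 3.01e-19, 2.5e-07 and 0.00119). The epididymis marker mean differed by 1.13 (camera adjusted p = 0.624) through 14-day array 4 alone, and by −0.22 without it (adjusted p = 0.554). The liver marker mean differed by 0.94 (adjusted p = 0.467) and ran from 0.28 to 1.70 as single arrays were left out.

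Cholesterol synthesis genes were again higher at 14 days, 19 of 20, with a median of 0.20 and array means of 10.12 ± 0.19 against 9.85 ± 0.05. Msmo1 and Insig1 differed by 0.46 ± 0.14 and 0.38 ± 0.13, and the mevalonate pathway genes Mvd and Fdps by 0.18 ± 0.07 and 0.88 ± 0.42. Mesothelial markers were lower in 7 of 10, with a median of −0.58; Wt1 and Bnc1 differed by −0.61 ± 0.19 and −0.70 ± 0.26, and the surface genes Upk1b and Upk3b by −0.54 ± 0.20 and −0.78 ± 0.30. Camera gave adjusted p = 3.83e-05 and 7.94e-05 for the 2 lists, each with adjusted p = 0.21 with an estimated correlation. Exact permutation p was 0.0857 and 0.0571. The cholesterol synthesis mean of 14-day array 2 was 9.85, at the chow level. Adjusted over the list alone, 6 mesothelial genes and 0 cholesterol synthesis genes passed in limma, with 3 cholesterol synthesis genes higher at unadjusted p under 0.05.

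Lists of the stroma and of other tissues were lower by smaller or less even steps. Preadipocyte and fibroblast markers were lower in 10 of 13 members, with a median of −0.22; the progenitor genes Pdgfra and Cd34 differed by −0.56 ± 0.12 and −0.50 ± 0.21. Extracellular matrix genes were lower in 15 of 26, with a median of −0.076; the collagen gene Col1a2, the collagenase activator gene Mmp14 and the proteoglycan gene Dcn differed by −0.53 ± 0.13, −0.45 ± 0.12 and −0.36 ± 0.10, and the 3 probe sets of Mmp14 ran from −0.55 to −0.11. Camera called both lower, at adjusted p = 0.00224 and 0.00643, with adjusted p = 0.607 and 0.904 with an estimated correlation. Both calls ended without 14-day array 4, where the fibroblast mean was −0.049 (adjusted p = 0.103) and the extracellular matrix mean 0.054 (adjusted p = 0.751), and with array weights (adjusted p = 0.175 for preadipocyte and fibroblast and 0.521 for extracellular matrix); without 14-day array 3 the extracellular matrix mean was −0.19. Branched-chain amino acid breakdown (12 of 16 lower), endothelium (13 of 14) and skeletal muscle (11 of 11) had camera adjusted p = 0.0223, 0.0223 and 0.0486, each with adjusted p = 0.904 with an estimated correlation. Branched-chain amino acid breakdown lost its call without chow array 1 or 3 or 14-day array 4 (highest adjusted p = 0.76, mean 0.039), and endothelium without chow array 3 or 4 or 14-day array 1, 3 or 4 (highest adjusted p = 0.394, mean −0.080). The mean of branched-chain amino acid breakdown was −0.15 without 14-day array 1 or 3, and that of endothelium −0.35 without 14-day array 2. Skeletal muscle lost its call without chow array 3, where its mean was 0.27 (adjusted p = 0.584), and without 5-day array 4 or 14-day array 1, 2 or 3, and kept it in 5 of 11 other planned settings. Those settings include eBayes without trend and in robust form, which do not enter camera and repeat the main result. Branched-chain amino acid breakdown also lost its call with array weights (adjusted p = 0.526).

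The tissue covariates also moved calls at 14 days. Both fits ended those of the extracellular matrix (means 0.0012 and 0.072), preadipocyte and fibroblast markers (−0.11 and −0.028), endothelium (−0.084 and 0.054) and branched-chain amino acid breakdown (−0.0041 and 0.0095). Cholesterol synthesis and mesothelium kept theirs in both, at 0.13 and −0.45 with the 3 covariates (adjusted p = 0.0053 and 0.0004). Fatty acid oxidation, at 0.039 and not called without covariates, passed as higher in both (0.11 and 0.074, adjusted p = 0.00426 and 0.00377). Fat mass expansion (0.40) and oxidative phosphorylation (0.072) passed as higher with the epididymis covariate only, and triglyceride storage (0.061) and adipocyte identity (0.073) with the 3 covariates only. Without 14-day array 4, fatty acid oxidation (0.14), fat mass expansion (0.47), triglyceride storage (0.092), adipocyte identity (0.13) and oxidative phosphorylation and nucleotide exchange (0.089) also passed as higher.

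No single gene passed at 14 days either: limma called 0 of 13312, with 1061 at unadjusted p under 0.05 (488 higher, 573 lower) and a lowest adjusted p of 0.362. All 4 arrays of 1 group lay above all 4 of the other in 4.63% of genes, where chance gives 2.86%. Here too other groupings gave more: 14-day arrays 1 and 3 with chow arrays 1 and 3 gave 2294 genes at unadjusted p under 0.05. Cd14 (probe set 1417268_at, chromosome 18, 36725064 to 36726815) had the smallest p, at 10.04 ± 0.31 against 10.90 ± 0.11 (SD, n = 4) and a difference of −0.86 ± 0.13. Next among the lower genes were Osr1 (−0.74 ± 0.12), the TAM receptor ligand Gas6 (−0.93 ± 0.16, −0.12 at its second probe set), the laminin chain Lamc3 (−0.37 ± 0.06) and Oasl2 (−0.76 ± 0.14). The higher genes of smallest p were Fhl1 (0.41 ± 0.08, 0.033 at its second probe set), Mrps6 (0.61 ± 0.13), Fam98a (0.32 ± 0.07), the acetyl-CoA transporter Slc33a1 (0.33 ± 0.07) and the proteasome activator Psme4 (0.33 ± 0.07). The heme synthesis gene Alas2, a red blood cell marker, differed by −0.97 ± 0.24. Counts rose to 2981 genes with array weights, 20 without 14-day array 2 and 2 without 14-day array 4.

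Of the genes fixed for every comparison, none passed at 14 days. Fasn and Adgre1 differed by −0.49 ± 0.23 and −0.39 ± 0.23. Lep, Mest and Sfrp5 differed by 0.20 ± 0.29, 0.35 ± 0.31 and 0.55 ± 0.45. Adipoq, Slc2a4 and Scd1 differed by −0.028 ± 0.04, 0.051 ± 0.16 and 0.020 ± 0.03, and probe sets of Slc2a4 and of Scd1 disagreed in sign. Ccl2 and Tnf differed by −0.30 ± 0.18 and −0.033 ± 0.08, and Hif1a and Nos2 by 0.13 ± 0.07 and 0.053 ± 0.08, with the probe sets of Hif1a between −0.25 and 0.16. Slc25a5 differed by 0.019 ± 0.06 and turned to −0.0077 under quantile normalization.

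**Figure D2:**
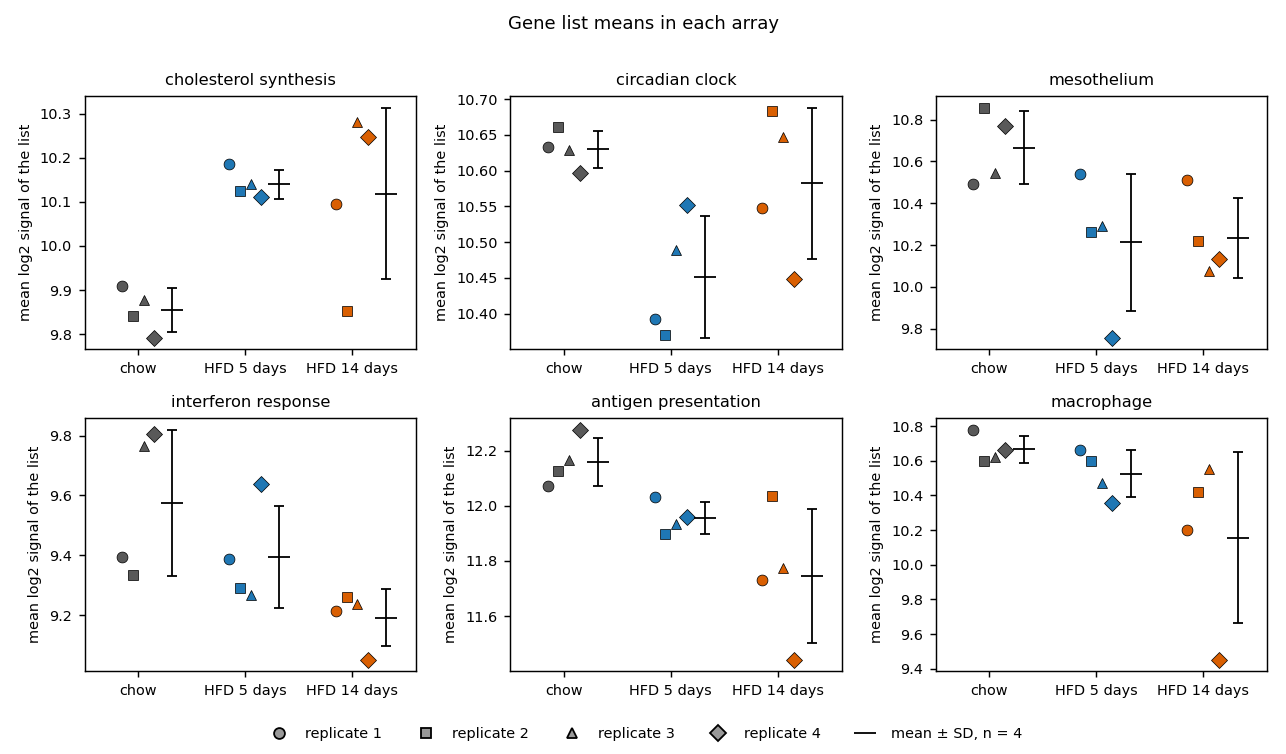
Mean log2 signal of 6 gene lists in each of the 12 arrays, by diet group; points are arrays with the marker shape giving the replicate, and bars are the mean ± SD (n = 4). All 4 14-day arrays lie under all 4 chow arrays for the interferon response, antigen presentation and macrophage lists, and all 4 5-day arrays lie above chow for cholesterol synthesis and under it for the circadian clock.

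The comparison of 14 with 5 days asks what differed between the times. The HFD groups began the diet at the same age, so the 14-day mice were older at collection. Age and diet time therefore cannot be told apart here. Macrophage markers were lower at 14 days in 20 of 21 members, with a median of −0.35, among them C1qa (−0.62 ± 0.26) and Cd68 (−0.48 ± 0.20). Extracellular matrix genes were lower in 24 of 26, with a median of −0.24; Col1a2 differed by −0.37 ± 0.13 and the collagen cross-linking enzyme gene Lox by −0.49 ± 0.21. Antigen presentation genes were lower in 11 of 12, with Cd74 and H2-Eb1 at −0.46 ± 0.18 each, and interferon response genes in 14 of 16, with Oas1a at −0.17 ± 0.07. Cell cycle genes were lower in 12 of 15, with a median of −0.067; the mitotic genes Cdk1, Plk1, Ube2c and Cdc20 differed by −0.38 ± 0.11, −0.21 ± 0.07, −0.48 ± 0.19 and −0.20 ± 0.08. Circadian clock genes were higher in 8 of 14, with Dbp at 0.49 ± 0.11, Ciart, a clock repressor, at 0.41 ± 0.12, Hlf at 0.35 ± 0.13 (0.16 at its second probe set) and Nr1d1 at 0.34 ± 0.14.

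Camera gave adjusted p = 6.83e-16 for macrophage markers, 3.28e-12 for the extracellular matrix, 5.03e-07 for antigen presentation, 8.6e-08 for the interferon response, 1.69e-05 for the cell cycle and 0.00127 for the circadian clock, each with adjusted p = 0.343 with an estimated correlation. Exact permutation p was 0.0286 for the interferon response and 0.0857 to 0.314 for the other 5 lists. Adjusted over the list alone, 2 circadian clock genes were higher. The epididymis marker mean differed by −1.46 in the same arrays and by −2.80 without 14-day array 4 (adjusted p = 0.00265), and 14-day array 4 carried the lowest macrophage and extracellular matrix means. Without it the macrophage mean of −0.37 was −0.13, the extracellular matrix mean of −0.21 was −0.048 and the antigen presentation mean of −0.21 was −0.11, with the calls kept. The interferon response mean of −0.20 was −0.12 without 5-day array 4. Leaving out both arrays numbered 4, chosen after seeing the data, ended the extracellular matrix, interferon response and cell cycle calls (adjusted p = 0.077, 0.161 and 0.077). The cell cycle call also ended with a 60th percentile filter (mean 0.010, adjusted p = 0.967) and the circadian clock call without 14-day array 2 (adjusted p = 0.0742) and with array weights (adjusted p = 0.0736).

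A further 11 lists passed camera between the times, and each lost its call with an estimated correlation, at adjusted p = 0.343 to 0.509. Lipid-handling macrophage markers were lower in 11 of 11 members (adjusted p = 6.48e-06) and had a mean of −0.068 in place of −0.15 without 14-day array 4. Endothelium was lower in 14 of 14 (adjusted p = 1.04e-05; 0.138 without 5-day array 4), and preadipocyte and fibroblast markers in 12 of 13 (adjusted p = 0.00078; 0.422 without 14-day array 4). Skeletal muscle was lower in 11 of 11 (adjusted p = 1.37e-05; 0.266 without 5-day array 2), with the myosin light chain gene Mylpf at −1.65 ± 1.21. Cytokines were lower in 15 of 21 (adjusted p = 0.00946; up to 0.65 without 5-day array 2 or 14-day array 4). Mast cell markers were lower in 5 of 6 (adjusted p = 0.00614; up to 0.108 without 5-day array 2 or 14-day array 3 or 4), and neutrophil markers in 6 of 7 (adjusted p = 0.0128; up to 0.353 without 5-day array 2 or 3 or 14-day array 1 or 2). Glucocorticoid targets were lower in 10 of 12 (adjusted p = 0.0128; up to 0.323 without 5-day array 4 or 14-day array 1 or 4), and heat shock genes higher in 9 of 11 (adjusted p = 0.0303; up to 0.36 without 5-day array 3 or 4 or 14-day array 1 or 4). Epididymis and testis markers were lower in 4 of 4 (adjusted p = 0.0339; up to 0.413 without 5-day array 2 or 3 or 14-day array 1, 2 or 3) and red blood cell markers in 4 of 4 (adjusted p = 0.0303; up to 0.433 without 5-day array 2 or 14-day array 2 or 4). Array weights kept the endothelium, mast cell and epididymis calls and ended the others of these 11. Other planned settings ended the heat shock call under quantile normalization (adjusted p = 0.0587) and with the mean of a gene's probe sets (adjusted p = 0.0783), the epididymis and testis call without an intensity filter (adjusted p = 0.613) and with the replicate block (adjusted p = 0.0603), and the red blood cell call without an intensity filter (adjusted p = 0.0999).

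Between the times both covariate fits ended the cytokine, circadian clock, neutrophil, mast cell and red blood cell calls, and the epididymis covariate ended that of skeletal muscle (adjusted p = 0.115). Both called 4 further lists lower: triglyceride storage (−0.12 and −0.11), adipocyte identity (−0.17 in both), fat mass expansion (−0.36 and −0.40) and branched-chain amino acid breakdown (−0.14 and −0.11). Without 14-day array 4 the first 2 and the last of these passed as higher instead (0.098, 0.11 and 0.10), so their direction depends on the setting.

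No single gene passed between the times: limma called 0 of 13312, with 340 at unadjusted p under 0.05 (235 higher, 105 lower) and a lowest adjusted p of 0.672. All 4 arrays of 1 group lay above all 4 of the other in 0.924% of genes, where chance gives 2.86%. Grouping 14-day arrays 1 to 3 with 5-day array 4 gave 4053 genes at unadjusted p under 0.05. The chemokine gene Ccl8 (probe set 1419684_at, chromosome 11, 82115185 to 82116799) had the smallest p, at 9.44 ± 0.23 after 14 days against 10.34 ± 0.27 after 5 (SD, n = 4), a difference of −0.91 ± 0.14. Cers4 differed by −0.43 ± 0.09, the estrogen sulfotransferase gene Sult1e1 by −0.92 ± 0.20, Taf5 by −0.21 ± 0.06 and the Notch ligand gene Dll4 by −0.46 ± 0.13. The higher genes of smallest p, beside Dbp, were Mtif2 (0.26 ± 0.06), A430033K04Rik (0.24 ± 0.06), Cep68 (0.32 ± 0.08, with 4 probe sets from −0.072 to 0.32) and Tmem230 (0.18 ± 0.05). Counts rose to 2212 genes with array weights. Of the fixed genes, Fasn differed by −0.48 ± 0.23, Lep by −0.28 ± 0.29, Mest by −0.33 ± 0.31, Adgre1 by −0.28 ± 0.23 and Ccl2 by −0.18 ± 0.18. Slc2a4, Scd1, Sfrp5 and Slc25a5 differed by −0.053 ± 0.16, −0.016 ± 0.03, −0.040 ± 0.45 and −0.055 ± 0.06, and Tnf, Hif1a and Nos2 by 0.053 ± 0.08, 0.042 ± 0.07 and 0.041 ± 0.08. Adipoq differed by 0.015 ± 0.04 and turned to −0.0045 under quantile normalization.

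Across the 13312 genes, the log2 differences from chow at 5 and at 14 days correlated with r = 0.81, and 78.2% had the same sign. Genes are not independent replicates, and both differences share the chow arrays. In 1000 simulated draws with no diet effect the mean r was 0.434 and 181 draws reached the observed value. With chow split so that each time had its own 2 control arrays, r lay between 0.431 and 0.662 over 6 splits. Without 14-day array 4, r was 0.403.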

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

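Every test of tissue RNA, of a single array and of exchanged labels, and the counts of splits for genes and lists without array weights, were chosen after the result was seen; the splits with array weights were set before.

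Cholesterol synthesis genes were higher at both times, by a list mean of 0.28 ± 0.08 (SE) at 5 days and 0.26 ± 0.08 at 14 days. The fit with the epididymis marker mean left shifts of 0.23 ± 0.10 (camera adjusted p = 0.0309) and 0.24 ± 0.09 (adjusted p = 0.000309). These p used the preset correlation, against 0.147 estimated for this list, so epididymal RNA alone stays open. Among HFD arrays without high epididymis markers, the list mean was 10.11 in 5-day array 4 and 10.09 and 10.28 in 14-day arrays 1 and 3. It was 9.85 in 14-day array 2, against 9.79 to 9.91 in chow. Liver RNA as the whole source is argued against by the fit with its marker mean, which hardly moved the shifts. They were 0.28 ± 0.09 (camera adjusted p = 0.000144) and 0.26 ± 0.09 (adjusted p = 0.000123), with the preset correlation here too. With epididymis, liver and skeletal muscle markers together, the 5-day shift was 0.12 ± 0.14 and its call ended (adjusted p = 0.185), both because the shift shrank and because its error grew, so a mixture of these tissues may account for it. At 14 days the shift was 0.13 ± 0.13 (adjusted p = 0.0053), where the mixture and the diet cannot be told apart because the error is as large as the shift.

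Macrophage markers were lower at 14 days by −0.51 ± 0.21. Array 4 of that group as the whole source is argued against by the fit without it (−0.27 ± 0.10). The fit with the epididymis marker mean left −0.41 ± 0.19, a shift with a wide error. Its camera call used the preset correlation, against 0.784 estimated for this list, so epididymal RNA alone stays open. A lower share of adipose RNA is argued against for arrays 1 to 3, where adipocyte genes stood above chow by 0.13 ± 0.07 and the macrophage list shifted by −0.40 ± 0.13 relative to them. It stays open for array 4, where adipocyte genes differed from chow by −0.47 and the macrophage list by −0.74 relative to them; with 1 array and high adipocyte signals, a loss of share could be partly hidden. Over all 4 arrays the relative shift was −0.49 ± 0.14, an average of arrays on both sides of chow that decides nothing. With the 3 tissue marker means together the shift was −0.14 ± 0.27 (adjusted p = 0.0242 by camera), so RNA of several neighbouring tissues may account for much of it. A change of macrophages with diet stays open and was not tested apart from these.

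The arrays numbered 4 of both HFD groups stood apart from their groups. Epididymal RNA in the arrays may account for this, since the marker mean of 14-day array 4 exceeded that of 5-day array 4 by 5.64 log2 units, against a chow SD of 0.56; Spink8 stood at 14.96 and 7.20 and Adam7 at 13.89 and 7.40, and 5-day arrays 1 to 3 also held these transcripts. An exchange of the labels of these arrays would place them at each other's group: on an axis from the 5-day (0) to the 14-day group (1) over 100 genes, 5-day array 4 stood at 1.04 and 14-day array 4 at −0.49. The chow arrays stood at a median of 0.989 on that axis, and the 100 genes were all higher at 5 days than in chow in arrays 1 to 3, so the axis follows tissue RNA. An exchange therefore cannot be told apart from uneven dissection, and no biological explanation was tested. RNA quality as a source was not tested either. The difference between 3' and 5' probe sets of pyruvate carboxylase was 2.83 in 5-day array 4 and 2.10 in 14-day array 4, against 1.70 to 1.91 in chow. For Gapdh it was 0.27 and 0.099, against 0.064 to 0.13 in chow.

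Counts of splits say nothing about chance for genes without array weights. In each comparison the real split gave 0 genes, so 35 of 35 splits had to give as many, and the highest of the others was 0 at 5 days against chow, 137 at 14 days against chow and 1496 at 14 against 5 days. The split with 1496 genes puts 14-day arrays 1 to 3 with 5-day array 4 and points to the structure of the samples described for the arrays numbered 4. The split with 137 genes puts chow array 1 in the place of 14-day array 2. Of all arrays, 14-day array 2 correlated highest with chow array 4 (0.997), and chow array 1 with 14-day array 3 (0.993). Chow array 1 still had a higher mean correlation with chow (0.990) than with the 14-day group (0.984). An exchange of these labels was not tested. For lists, 19, 28 and 4 of 35 splits gave as many as the real 9, 12 and 17, with highest others of 18, 21 and 22, so chance cannot be excluded in any of the 3 comparisons. With array weights, 5 days against chow gave 2015 genes and 1 of 35 splits gave as many, with 1354 as the highest other. This is the smallest share that 35 splits can give, 5 other splits gave genes too, and it is 1 of 3 comparisons tested. Chance is therefore not excluded. In the split with 1354 genes, chow array 1 took the place of 5-day array 4. It kept together 5-day arrays 1 to 3, which had high epididymis markers. With those weights 4 of 35 splits matched the 2981 genes of 14 days against chow and 5 of 35 the 2212 of 14 against 5 days, with highest others of 3936 and 3481, so chance cannot be excluded for them.

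A single array lay far from the other 3 of its group in 28 of 420 groups of values, where chance gives about 21; the value after each name is the gap to the nearest array over the whole range. In 5-day array 4 these were Spink8 (0.976), Adam7 (0.961), Psme4 (0.921), Fdps (0.907), the mammary and surface epithelium list (0.899), Wt1 (0.881), Scd2 (0.860) and Col4a1 (0.846). In 14-day array 4 they were Adam7 (0.954), the hypoxia response list (0.898), the epididymis and testis list (0.895), the lipid-handling macrophage list (0.888), Lox (0.838) and Wt1 (0.832). In chow array 1 they were C1qc (0.931), the pancreas list (0.863), the nerve and Schwann cell list (0.856), Osr1 (0.840), A430033K04Rik (0.840) and Slc25a5 (0.837). In chow array 3 they were Col4a1 (0.968), the skeletal muscle list (0.952) and Mylpf (0.925), and in chow array 2 Nr1d1 (0.946) and Mtif2 (0.837). In 5-day array 2 they were Tmem230 (0.894) and the skeletal muscle list (0.830), and in 5-day array 3 the unfolded protein response list (0.844).

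Between 5 and 14 days of HFD camera called 17 lists, and 4 of 35 splits gave as many. Fits with the epididymis covariate and with the 3 tissue covariates both ended the cytokine, circadian clock, neutrophil, mast cell and red blood cell calls. Both kept the macrophage, lipid-handling macrophage, interferon response, antigen presentation, extracellular matrix, cell cycle, glucocorticoid, heat shock, endothelium and fibroblast calls. These fits cover only the tissues with markers, and neither other unevenness of dissection nor age at collection was tested apart from the diet. None of the lists passed with an estimated correlation (lowest adjusted p = 0.343). Mean shifts from 5 to 14 days were −0.37 for macrophage, −0.15 for lipid-handling macrophage, −0.33 for neutrophil and −0.12 for mast cell markers. They were −0.11 for cytokines, −0.20 for the interferon response, −0.21 for antigen presentation, −0.21 for the extracellular matrix, −0.15 for the cell cycle and −0.086 for glucocorticoid targets. They were −0.25 for endothelium, −0.19 for preadipocyte and fibroblast, −1.22 for skeletal muscle, −1.46 for epididymis and testis and −0.22 for red blood cell markers, and 0.13 for the circadian clock and 0.12 for heat shock genes.

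Signals outside the tested genes also stood out. The poly-A spike-in probe sets, RNA added during labelling, averaged 8.99 in 5-day array 4, 8.03 in 5-day array 1 and 8.20, 8.15 and 8.25 in 14-day arrays 1 to 3, above the highest chow array (7.97). They averaged 7.83 and 7.80 in 5-day arrays 2 and 3 and 7.78 in 14-day array 4, within the chow range from 7.61. Spike-in RNA does not come from the tissue, and its bearing on exchanged labels was not tested. Among 4062 probe sets with no gene symbol, limma called 1 at 5 days, probe set 1440490_at, at 7.60 against 8.22 and a difference of −0.62 ± 0.09 (adjusted p = 0.0452). It called 0 at 14 days and 0 between the times, with 215 and 61 at unadjusted p under 0.05.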

How the results depend on the processing

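The covariates and the joint removal of both HFD arrays numbered 4 were chosen after the data were seen; the other alternatives were planned. The count of 0 called genes in each comparison (limma; 1345, 1061 and 340 at unadjusted p under 0.05) held under scaling, filter, probe set and variance alternatives, the replicate block and a threshold of 0.1. It moved to 2015 (1064 higher, 951 lower), 2981 (1951 higher, 1030 lower) and 2212 (1366 higher, 846 lower) genes with array weights, which gave 14-day array 4 a weight of 0.106 and 5-day array 4 a weight of 0.255. It moved to 213 genes (129 higher) at 5 days against chow with only those groups, a fit that drops the spread of the 14-day arrays. The epididymis covariate gave 502 genes (423 higher) at 5 days against chow and 35 (32 lower) at 14 against 5 days, and the 3 tissue covariates gave 0, 0 and 0. Leaving out both arrays numbered 4 gave 881, 1 and 723 genes. Leaving out single arrays gave 0 to 123 genes at 5 days against chow (123 without 14-day array 4, 1 without 14-day array 2), 0 to 20 at 14 days against chow (20 without 14-day array 2, 2 without 14-day array 4) and 0 at 14 against 5 days. The cause of the other moves was not tested.

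Shifted lists (9, 12 and 17) stayed within 1.5 times in 32 of 39 planned counts, single removals apart. The counts for eBayes without trend and in robust form repeat the main ones, since camera does not use those options. They therefore say nothing about stability, also where planned settings are tallied for single lists. They went to 5 at 5 days against chow under quantile normalization, to 0, 0 and 0 with an estimated correlation and to 0, 0 and 0 with fry, and single removals ran from 11 (without 5-day array 2) to 21 at 14 against 5 days. At 5 days against chow the epididymis covariate gave 14 lists (10 higher) and the 3 covariates 16 (13 higher), against 3 higher of the 9. Without 14-day array 4 the lists at 14 days against chow were 13 with 6 higher, in place of 12 with 1 higher, and those at 14 against 5 days 19 with 6 higher, in place of 17 with 2 higher. The replicate block gave 9, 12 and 16; only 2 of 12 same-number pairs correlated above 0.1, so the numbers were not read as pairs. The correlation of effects (0.81) ran from 0.403 (without 14-day array 4) to 0.84 as single arrays were left out.

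Of 3891 alternative values for 151 gene values, 3619 kept direction and side of the threshold, 212 passed it newly, 0 lost it and 60 turned direction. The cause was not tested. The 0 was fixed in advance, since no gene passed in the main fits. Direction could not turn under the variance alternatives, the replicate block or the fit of only 2 groups. Nor could it turn without an array outside the comparison, so much of the 3619 does not show stability. Those that turned had log2 differences as follows. Median centring gave Fasn 0.0020 (5 days against chow). Quantile normalization gave Slc25a5 −0.0077 (14 days against chow), and Adipoq −0.0045 (14 against 5 days). The mean of a gene's probe sets gave Hif1a −0.021 (5 days against chow), and Scd1 −0.0027, Hif1a −0.022 (14 days against chow), and Hif1a −0.00063 (14 against 5 days). Array weights gave Fasn 0.0081 (5 days against chow), and Adipoq 0.014, Tnf 0.0011 (14 days against chow), and Lep 0.19, Slc2a4 0.22, Mest 0.29, Sfrp5 0.92 (14 against 5 days). The epididymis covariate gave Fasn 0.19, Adgre1 0.22 (5 days against chow), and Adipoq −0.0061, Hif1a −0.00026 (14 against 5 days). The 3 tissue covariates gave Adipoq 0.0028, Fasn 0.16, Adgre1 0.53, Ccl2 0.16, Msmo1 −0.075, Fga −0.20 (5 days against chow), and Mest −0.0034, Adgre1 0.070, Ccl2 0.019, Tnf 0.019 (14 days against chow), and Adipoq −0.0038, Hif1a −0.038, Nos2 −0.0028 (14 against 5 days). Leaving out both HFD arrays numbered 4 gave Adipoq 0.0031, Tnf 0.0019 (14 days against chow), and Lep 0.11, Slc2a4 0.14, Scd1 0.0027, Mest 0.045, Sfrp5 0.57 (14 against 5 days). Over single removals the ranges of genes that turned follow. For 5 days against chow they were Fasn −0.096 to 0.072, Nos2 −0.047 to 0.074. For 14 days against chow they were Tnf −0.082 to 0.011, Nos2 −0.0062 to 0.11, Slc2a4 −0.049 to 0.22, Slc25a5 −0.039 to 0.048, Adipoq −0.046 to 0.0031. For 14 against 5 days they were Hif1a −0.013 to 0.080, Sfrp5 −0.48 to 0.39, Tnf −0.0068 to 0.094, Adipoq −0.0039 to 0.045, Lep −0.47 to 0.0050, Slc2a4 −0.15 to 0.11, Scd1 −0.027 to 0.0030. Alternatives for values on a linear scale were not run, since the values are log2. Of genes in the table, Ucp1 lay under the filter, where signal is near background.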

Other observations

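The test of both HFD times pooled against chow was set before its result was seen; the levels by array given here were picked after the values were seen.

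The cell cycle list did not pass at 5 days. Of its 15 measured genes 8 were higher and 7 lower, with camera adjusted p = 0.0753, adjusted p = 0.894 with an estimated correlation and 2 genes higher when adjusted over the list alone. The mitotic kinase gene Cdk1 differed by 0.50 ± 0.11, the ubiquitin-conjugating enzyme gene Ube2c by 0.66 ± 0.19, the proliferation marker Mki67 by 0.90 ± 0.32 and Cdc20 by 0.24 ± 0.08, but the replication gene Mcm4 by −0.19 ± 0.08 and Mcm6 by −0.14 ± 0.09 (n = 4 arrays per group). Genes that track fat mass expansion were higher in 5 of 6 members, with a median of 0.51 and camera adjusted p = 0.0753. The desaturase gene Scd2 differed by 1.08 ± 0.35, and the basement membrane and fibrillar collagen genes Col4a1 and Col5a3 by 0.33 ± 0.11 and 0.76 ± 0.28. The progenitor gene Pdgfra differed by −0.48 ± 0.12. None of these genes passed the test.

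With both times pooled, HFD against chow gave 0 genes at adjusted p under 0.05 in limma, with 1576 at unadjusted p under 0.05 (747 higher, 829 lower). The hypothesis that pooling would bring out a shared effect of the diet thus found no called gene: the lowest adjusted p was 0.0944, shared by Osr1 (−0.71), Lamc3 (−0.37), Podn (−0.61), Fhl1 (0.41), Mrps6 (0.68), St3gal6 (−0.60) and Gas6 (−0.84). Since the real count was 0, 100 of 100 splits of the 12 arrays had to give as many, which says nothing about chance; the highest other gave 1 gene.

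Foxj1, a gene of ciliated cells, stood at 10.33, 9.84 and 10.11 in chow arrays 2 to 4 and at 9.92 in 14-day array 2, and between 7.57 and 8.84 in the other arrays. Cldn2 and Tmem212 stood at 12.03 and 11.36 in chow array 2, at 8.05 and 8.14 in chow array 1 and at 11.70 and 10.94 in 14-day array 2. Of all pairs of arrays, chow array 4 and 14-day array 2 correlated highest (0.997). On an axis from chow (0) to 5 days (1) over the 100 genes of smallest p in that comparison, 14-day arrays 1 to 4 stood at 0.588, 0.38, 0.931 and 0.95. The Y-linked gene Kdm5d lay between 8.50 and 9.02 in all 12 arrays and Xist between 8.63 and 8.96. The difference between 3' and 5' probe sets of pyruvate carboxylase ran from 1.70 to 1.91 in chow. It was higher in 5-day arrays 3 and 4 (1.94 and 2.83) and in 14-day arrays 1, 2 and 4 (1.96, 2.18 and 2.10). The same difference for Gapdh ran from 0.064 to 0.13 in chow and was 0.27 in 5-day array 4 and 0.28 in 14-day array 2.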
